A study of Danio rerio with 8 samples.

How the data were processed

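Poly-A RNA of dissected livers from untreated adult zebrafish of about 1 year was sequenced by the submitters. The series compares the wild-type line TAB14 with a line carrying a CRISPR mutation of as3mt, the gene of arsenite methyltransferase, which adds methyl groups to inorganic arsenic. The mutation is described as a deletion of 8 bp in exon 3 that brings in a premature stop codon. There were 2 female and 2 male livers of each genotype, 8 libraries in all, 1 library per fish. Per the labels, RNA had an RNA integrity number above 7, input was 100 ng and amplification took 12 PCR cycles. The birth date given for the wild-type fish is 15 March 2022 and for the mutant fish 19 January 2022. Genotype therefore goes together with line and birth cohort. The growth protocol speaks of larvae although the fish were adults, and 2 different library kits are named, so the strandedness of the libraries is not known here.

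The deposited values were counts per Ensembl gene ID, whole numbers for 32105 IDs in each library, with no normalisation applied by the authors. The tools named for the authors' processing were FastQC 0.11.5 and Trimmomatic 0.36. The aligner, the counter, the genome build, the annotation release and the strand setting were not given in the sources used here. A symbol was available for 26269 of the IDs, and 4301 IDs shared their symbol with another ID. Reads of such copies may be shared between them. No genome coordinates are given, since the build of the counts was not known.

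The names of the deposited files give the 2 genotypes the other way round from the sample labels. The labels were followed throughout, and every direction between genotypes is stated for libraries as labelled. The level of as3mt was given for each library before any direction, but it does not check the labels, because an 8 bp deletion leaves the transcript countable.

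The submitters left wild-type female 2 out of their analyses. Since the file names reverse the genotypes, the library meant may be the one labelled mutant female 2, so leaving that one out in its place was among the alternatives. The comparisons here used the other 7 libraries: 3 labelled wild type and 4 labelled mutant, or 3 female and 4 male. Total counts per library ran from 31958111 to 52129208. A count of 0 in a group was given an upper limit of 3 counts over the whole group, and a fold against such a group was computed against that floor and written as "at least". A gene with 1 to 3 counts in a group was given as a ratio with its 95% counting interval (exact Clopper-Pearson). These intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

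Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype groups, a minimum count of 10 and a minimum total of 15, which left 14885 genes. Libraries were scaled by the trimmed mean of M values (TMM), and normalised CPM values are the edgeR cpm of counts over the TMM-scaled library size. Genes were tested with the edgeR quasi-likelihood F test with robust estimation and a prior count of 0.125 for fold changes. P-values were adjusted by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Genotype (mutant minus wild type) and sex (male minus female) were tested in 1 additive fit of sex and genotype, with 4 residual degrees of freedom. A fit of the 4 groups, with 3 residual degrees of freedom, gave the interaction, which is the mutant minus wild-type difference in males minus that in females. It also gave the genotype difference within each sex. The wild-type female group then held 1 library, which was assumed to vary like the libraries of the other groups. The standard error (SE) of a log2 fold change was its unshrunken size divided by the square root of the F statistic. The 95% interval of as3mt used the residual degrees of freedom. Values given as mean ± SD are over the libraries of the fit.

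Before the data were examined, 38 gene lists were fixed, 24 of pathways or complexes and 14 of cell types that dissected liver could hold. Of their 1263 symbols, 975 matched by symbol, 108 by synonym and 90 after removal of a paralog suffix, and 90 stayed unmatched. The symbol cd3eap was left out of the lymphocyte list because it names a subunit of RNA polymerase I. The 34 lists with at least 5 tested members were tested with camera from limma 3.58.1, 2-sided, with a preset inter-gene correlation of 0.01. Their p-values were adjusted over the 34 lists, and the test was repeated with a correlation estimated for each list. Members of a list were also adjusted over the list alone. The level of a list in a library was the median over its genes of log2(CPM + 1) minus the gene's mean over the 7 libraries.

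The named genes followed a rule fixed before the data were examined. It took as3mt, and for genotype and sex the 10 highest and 10 lowest log2 fold changes among called genes with at least 5 CPM in the higher group and with every library of one class beyond every library of the other within both strata. Clone-named genes were limited to 3 each way beside these. It also took up to 4 called members of each list, or the 2 members with the highest CPM as values where none was called. For the interaction it took the 10 lowest adjusted p-values. Genes named outside this rule are said to be so where they appear.

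No 2 libraries held identical counts. Spread between fish of a group exceeded counting noise, with a chi-square per degree of freedom of 99.6 to 246 over genes with at least 10 counts in the group.

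The tests were tried on simulated data with 200 changed genes, 50 at each fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not tried. All other simulated genes had the same expected level in every library, without a difference between sexes or genotypes. The genotype test recovered 0 at a fold of 2, 17 at 4, 35 at 8 and 42 at 16, with 4 false calls. The sex test recovered 0, 13, 36 and 49 at the same folds, with 5 false calls. The interaction test recovered 4 at a fold of 4, 31 at 16, 44 at 64 and 47 at 256, with 23 false calls. The test in males recovered 13, 48, 49 and 49 at those folds, with 14 false calls. The folds for the interaction were raised after a simulation with folds of 2 to 16 and another spread had recovered 0. A log2 shift of 1 in the interferon list was called by camera at an adjusted p of 2.99e-19, with 0 of the 33 other lists called. Simulated genes were drawn independently of each other, so this does not try the list test under correlation between genes.

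The alternatives were DESeq2 size factors, TMM without the vitellogenin genes, no low-count filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample weights and all 8 libraries. Further ones were mutant female 2 left out in place of wild-type female 2, each library left out in turn, no sex or no genotype term, the number in the label as a block, an adjusted p under 0.01, a fold of at least 1.5 and the estimated correlation of lists. Leaving out mutant female 1 in place of wild-type female 2 was added after the data showed that library apart from the others. The interaction was tested over the lists after the data were seen, as further description.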

Results

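The data are gene counts from 8 adult zebrafish livers, 2 females and 2 males labelled wild type (TAB14) and 2 females and 2 males labelled as3mt mutant. Among libraries labelled wild type, total counts were 31958111 in female 1, 34239016 in female 2, 34918693 in male 1 and 34560983 in male 2. Among libraries labelled mutant they were 52129208 in female 1, 38127505 in female 2, 32719723 in male 1 and 35271538 in male 2. The 8 vitellogenin genes took 48.5% to 64.2% of the counts of each female library and 0.0035% to 0.014% of each male library, so the other genes of a female share a smaller part of its counts. The comparisons rest on 7 libraries, without wild-type female 2, which the submitters left out, and on 14885 tested genes.

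The series asks how liver transcripts differ between as3mt mutant and wild-type fish. The transcript of as3mt itself (ENSDARG00000027572), the methyltransferase of inorganic arsenic, was present in every library. Among libraries labelled wild type its level was 43.2 CPM in female 1, 41.2 in male 1, 24.5 in male 2 and 43.7 in the left-out female 2. Among libraries labelled mutant it was 29.4 in female 1, 51.4 in female 2, 66.3 in male 1 and 57.1 in male 2. The mean was 36.3 ± 10.3 CPM (SD, n = 3) for labelled wild type and 51.1 ± 15.7 CPM (SD, n = 4) for labelled mutant. The log2 fold change of as3mt was 0.49 (SE 0.344, 95% interval -0.46 to 1.45, edgeR adjusted p = 1.00), a fold of 1.41 with bounds of 0.73 and 2.73, so no difference was detected. It was 0.91 in males (SE 0.388, adjusted p = 0.584) and -0.10 in females (SE 0.471, adjusted p = 0.945), and the interaction was not called (SE 0.603, adjusted p = 0.462). The deposited file names give the genotypes the other way round from the labels, so directions hold for labels only.

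**Figure D1:**
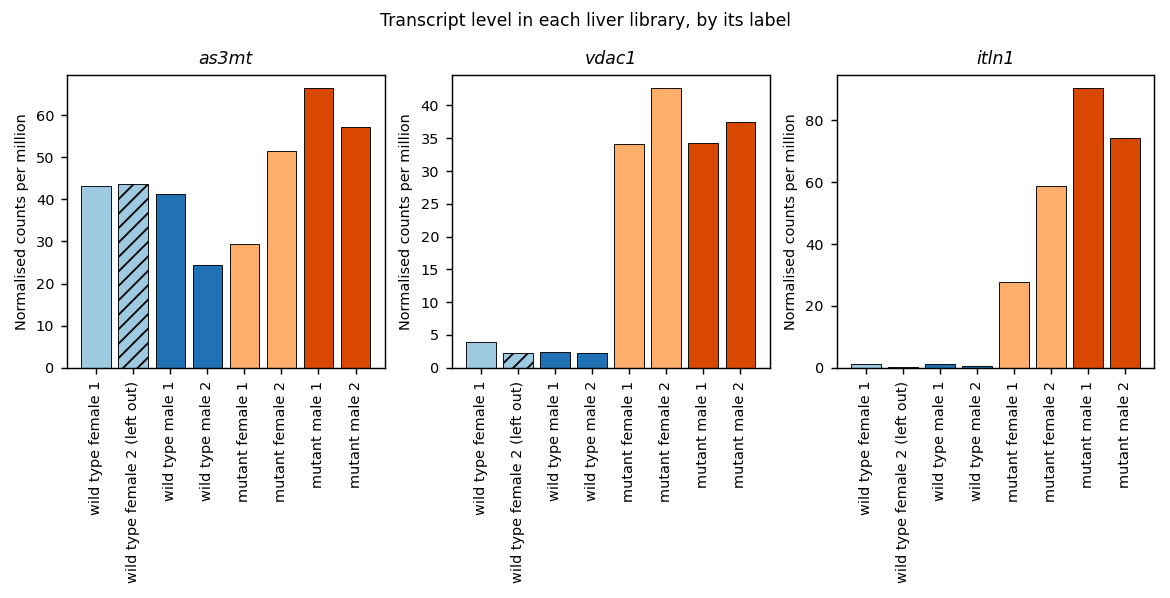
Normalised CPM (vertical axes, linear from 0) of as3mt, vdac1 and itln1 in each of the 8 libraries, 1 bar per library, with the left-out wild-type female 2 hatched. The level of as3mt overlaps between the labels, while vdac1 has a mean of 2.86 CPM in the 3 libraries labelled wild type and 37.1 CPM in the 4 labelled mutant.

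Between the labelled genotypes 9 genes were called, 8 higher and 1 lower in libraries labelled mutant. The transcript of vdac1 (ENSDARG00000045132), a channel of the outer mitochondrial membrane, rose from 2.86 ± 0.91 CPM (SD, n = 3) to 37.1 ± 3.98 CPM (SD, n = 4), a log2 fold change of 3.68 (SE 0.258, edgeR adjusted p = 0.0205). The transcript of itln1 (ENSDARG00000095082), an intelectin, a lectin that binds microbial sugars, rose from 0.974 ± 0.306 to 62.8 ± 26.7 CPM, a log2 fold change of 6.02 (SE 0.537). Of the clone-named genes, si:dkey-61p9.9 rose from 0.365 ± 0.101 to 12.3 ± 3.91 CPM, and si:ch211-254c8.3 had 0 counts in the 3 libraries labelled wild type and 12.9 ± 6.30 CPM in those labelled mutant, at least 539-fold higher. The gene si:ch211-213a13.11 fell from a mean of 5.89 to 0.206 ± 0.086 CPM, a log2 fold change of -4.84 (SE 0.441).

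The 4 other called genes lay under 5 CPM and are named here after their values were seen. The calcium channel gene cacna1g rose from 0.062 to 4.73 CPM and vwa7 from 0.065 to 4.09 CPM. The second intelectin gene, itln2, had 1 count against 300 counts, a ratio of 251.7 (44.8 to 9975), and ccdc134 had 1 count against 434, a ratio of 364 (65.0 to 14420). Short of the threshold by a small margin, and also chosen after the values were seen, 2 copies of ggact, a gamma-glutamylamine cyclotransferase, had 6.27 and 6.32 CPM in libraries labelled wild type and 0 counts in those labelled mutant, at least 312-fold and 315-fold lower (adjusted p = 0.0507 for both). Another copy of ggact had 1.03 CPM against 0 counts, at least 51.3-fold lower (adjusted p = 0.211). The adhesion molecule gene dscam had 0 counts against 34.6 CPM, at least 1443-fold higher (adjusted p = 0.0678). The left-out wild-type female 2, which was not in the fit, lay on the wild-type side for 9 of the 9 called genes.

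The edgeR count depended on the libraries in the fit. It was 0 without wild-type male 1, wild-type male 2, mutant male 1 or mutant male 2, with 561 to 738 genes at an unadjusted p under 0.05. It was 27 without mutant female 1 and 21 without mutant female 2. Without wild-type female 1 it was 17, but no wild-type female then remained, so that count compares males only. The log2 fold change of vdac1 was 3.94 in males and 3.29 in females, with an interaction that was not called (0.65, SE 0.373, adjusted p = 0.450). At an unadjusted p under 0.05 stood 778 genes where chance gives 744, and DESeq2 called 233 and limma-voom 72, the 9 genes among them in both. The additive fit averages the sexes, whose genotype differences had the same sign in 37.6% of genes with a mean of at least 5 CPM. Opposed differences cancel in it, so the 778 genes do not measure the difference within each sex.

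Of the 34 gene lists, 2 were called between the labelled genotypes. Interferon response transcripts, which antiviral signalling raises, were higher as a group in libraries labelled mutant, with 37 of 41 log2 fold changes positive, a median of 0.78 and a camera adjusted p = 2.37e-06. With an estimated correlation the call was lost (adjusted p = 0.919 with an estimated correlation), and 0 of the 41 members were called, over all genes or adjusted over the list alone. The members with the highest CPM had log2 fold changes of 0.78 for stat2 (SE 0.217) and 0.01 for b2m (SE 0.334). The level of interferon response was -0.60 in wild-type female 1, -0.71 in the left-out female 2, -0.03 and -0.23 in the wild-type males, 0.68 in mutant female 1 and 0.20 and 0.57 in the mutant males. In mutant female 2 it was -0.90, the lowest of the 8 libraries and against the direction of the group. Without mutant female 1 the median was 0.32 (camera adjusted p = 0.00469).

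Exocrine pancreas markers, the digestive enzymes of acinar cells, were the other list, with 30 of 30 members positive, a median of 2.27 and a camera adjusted p = 0.00551 (adjusted p = 0.919 with an estimated correlation). No member was called, and prss59.1 had a log2 fold change of 2.42 (SE 1.88) and ctrb.1 of 2.55 (SE 1.87). The level of exocrine pancreas markers varied within every group: -1.56 in wild-type female 1, 1.63 in the left-out female 2, -0.66 and 1.52 in the wild-type males, 1.95 and -2.53 in the mutant females and 3.57 and -1.51 in the mutant males. The call was lost with all 8 libraries (median 0.89, camera adjusted p = 0.579), without wild-type female 1 (males only, 0.0629), without wild-type male 1 (0.0668) and without mutant female 1 (median 0.84, 0.809). Without mutant male 1 the camera direction turned while the median was 0.17 (adjusted p = 0.834), as it did with mutant female 1 left out in place of wild-type female 2 (median 0.34, 0.367).

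**Figure D2:**
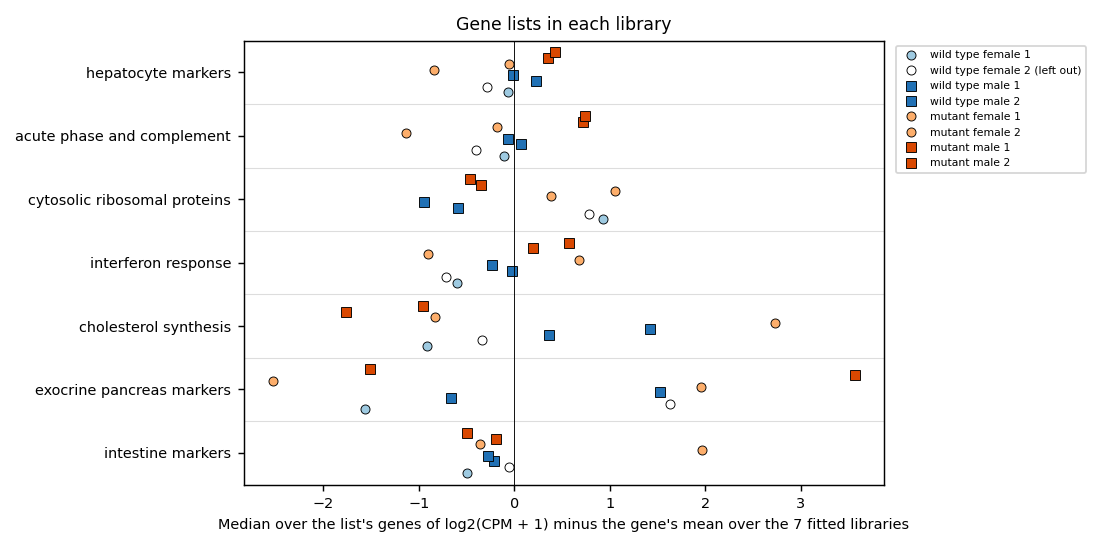
Level of 7 gene lists in each of the 8 libraries, as the median over a list's genes of log2(CPM + 1) minus the gene's mean over the 7 fitted libraries (horizontal axis), with circles for females, squares for males, blue for labelled wild type, orange for labelled mutant and white for the left-out library. Mutant female 1 stands alone at 1.96 for intestine markers and 2.73 for cholesterol synthesis, and exocrine pancreas markers range from -2.53 to 3.57.

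No list of arsenic or methyl-group metabolism was called between the labelled genotypes. In the methionine and one-carbon cycle (median 0.08, camera adjusted p = 0.200) the log2 fold change was 0.14 for ahcy and -0.24 for bhmt. One member, pemt, which makes phosphatidylcholine with methyl groups of S-adenosylmethionine and was named after its values were seen, had 1.48 CPM against 4.92 CPM, a log2 fold change of 1.74 (SE 0.307), with an adjusted p = 0.0182 adjusted over the list alone and 0.211 over all genes. In arsenic handling and metal binding (median 0.01, adjusted p = 0.637) the log2 fold change was -0.36 for pnp4b and 0.03 for abcc2, and in Nrf2 targets and glutathione (median 0.02, adjusted p = 0.713) it was 0.20 for cat and 0.47 for gpx4a.

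Markers of other tissues and a lipid pathway stood out in mutant female 1 and belong beside these results. Its intestine level was 1.96, against -0.50 to -0.06 in the 7 other libraries. The fatty acid binding protein gene of enterocytes, fabp2, had 699 CPM there and 2.90 to 92.8 elsewhere. The other member named by the rule, apoa4b.1, did not stand out, with 530 CPM there and 252 to 1418 elsewhere. Its cholesterol synthesis level was 2.73, with hmgcs1, an early enzyme of the pathway, at 1815 CPM, and its acute phase and hepatocyte levels were -1.14 and -0.84. The intestine list itself was not called (median 0.63, camera adjusted p = 0.0911), nor was cholesterol synthesis, with 22 of 25 members negative (median -1.01, adjusted p = 0.124).

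The remaining lists were not called between genotypes. Under an adjusted p of 0.1 stood heat shock (median 0.22, camera adjusted p = 0.0805), nuclear-encoded respiratory chain (0.16, 61 of 70 positive, 0.0805), biliary and epithelial markers (-0.30, 0.0805) and stellate and fibroblast markers (0.52, 0.0805). The next were apolipoproteins (0.17, 0.100), cytosolic ribosomal proteins (0.12, 77 of 79 positive, 0.124), acute phase and complement (0.21, 0.124), cell cycle (-0.96, 0.124), bile acid synthesis (0.22, 0.124) and endothelial markers (0.25, 0.124). Unfolded protein response (-0.29, 0.198), circadian clock (0.14, 0.198), myeloid (-0.37, 0.278), egg proteins (-0.05, 0.379), gluconeogenesis and glycolysis (0.04, 0.414) and p53 targets (0.08, 0.452) followed. Last came erythrocyte (-0.20, 0.533), adipocyte (0.04, 0.533), lymphocyte (-0.19, 0.614), fatty acid oxidation (-0.04, 0.627), proteasome (-0.04, 0.637), amino acid metabolism (0.02, 0.637), fatty acid synthesis (-0.11, 0.713), DNA methylation (0.01, 0.713), mitochondrially encoded genes (-0.05, 0.726), xenobiotic metabolism (-0.12, 0.827) and hepatocyte markers (0.05, 0.876). Median, mean or test differed in sign for arsenic handling, fatty acid oxidation, amino acid metabolism, DNA methylation and myeloid markers. Of the lists too small to test, ovary and oocyte had 1 tested member, testis 3, skeletal muscle 4 and endocrine pancreas 0.

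The sex of each fish gives the second comparison. Transcripts of the egg yolk precursors, which the liver of females makes under estrogen, dominated it. Expression of vtg1 was 444957 CPM in females (n = 3) and 19.1 in males (n = 4), a log2 fold change, male minus female, of -14.51 (SE 0.65, edgeR adjusted p = 0.000119). Expression of vtg2 was 148850 against 5.67 CPM (-14.70), of vtg3 15031 against 0.547 (-14.74) and of vtg5 83240 against 23.1 (-12.69). The changes were -14.53 for vtg4, -14.21 for vtg6, -14.58 for vtg7 and -13.31 for vtg8. The sex labels and these genes separate the 8 libraries alike.

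Of 248 genes called between sexes, 99 were higher in males and 149 in females. Besides vitellogenins, fam20cl had 883 ± 386 CPM in females and 1 count in the 4 males, a ratio of 152000 (27280 to 6004000), and iyd, an iodotyrosine deiodinase, had 45.0 ± 6.16 CPM against 1 count, a ratio of 8559 (1535 to 338100). The unnamed genes ENSDARG00000103451 and ENSDARG00000093425 changed by -14.16 and -13.99 and si:ch73-7i4.2 by -8.63.

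Higher in males were cyp2k22, a cytochrome P450 (0.083 against 642 ± 196 CPM, log2 fold change 12.99), slc27a6, a fatty acid transporter (0.212 against 255 CPM, 10.23), and hsd17b3, which makes testosterone from androstenedione (0.199 against 135 CPM, 9.44). In females trim35-9 and cyp2k31 had 0 counts, so males were at least 252-fold and 136-fold higher. The changes were 8.74 for cd59a, 8.04 for fat2, 8.00 for igsf9ba, 7.94 for slc38a3 and 6.73 for csad, an enzyme of taurine synthesis. They were 7.18 for si:ch211-220m17.4, 6.13 for si:dkey-71h2.2 and 5.84 for zgc:153031.

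**Figure D3:**
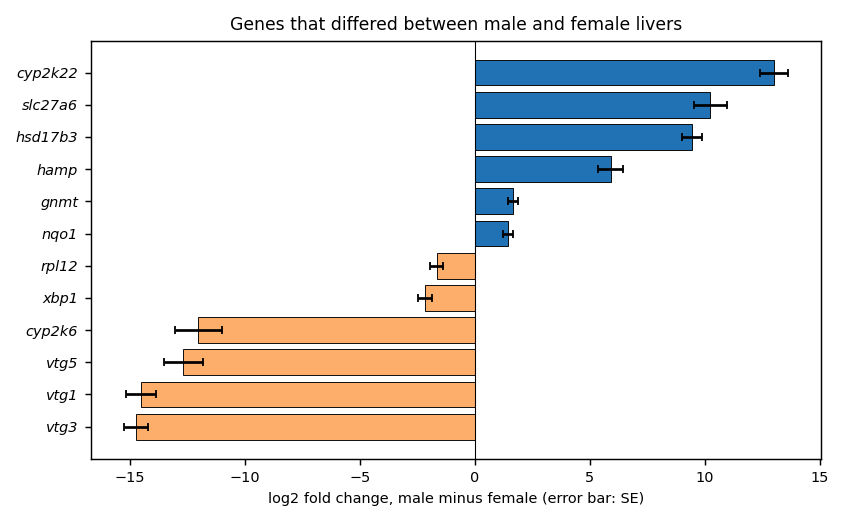
Log2 fold change, male minus female, of 12 called genes (horizontal axis), 1 bar per gene with its SE as error bar, blue for higher in males and orange for higher in females. The bars run from -14.74 for vtg3 to 12.99 for cyp2k22.

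The number called between sexes moves with the libraries. It was 149 without wild-type female 1, where the sexes are compared among labelled mutants only. It was 94 without wild-type male 1, 119 without wild-type male 2, 387 without mutant female 1 and 82 without mutant female 2. Without mutant male 1 it was 105 and without mutant male 2 it was 82. All 8 libraries gave 773 and DESeq2 1056, and of the 48 named genes 17 to 20 lost their call without wild-type female 1 or any 1 male. Without mutant female 2, 21 of the 42 that could be followed did so, and without mutant female 1 0 of 42.

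In the sex comparison 14 of the 34 lists were called. Egg proteins were lower in males, 9 of 9 members called (median -14.51, camera adjusted p = 6.84e-152, adjusted p = 0.00915 with an estimated correlation). Cytosolic ribosomal proteins, the parts of the ribosome, were lower in males, with 78 of 79 members negative, a median of -1.37 and a camera adjusted p = 1.44e-42 (adjusted p = 0.680 with an estimated correlation). Of these, 11 were called lower, and 78 lower with 1 higher adjusted over the list alone, among them rpl12 (2024 against 632 CPM, -1.67, SE 0.268), rps20 (-1.70), rps12 (-1.66) and rplp2l (-1.63). With the vitellogenin genes left out of the scaling the direction of the list was the same.

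Acute phase and complement transcripts, secreted proteins of hepatocytes, were higher in males, with 41 of 45 positive (median 0.73, camera adjusted p = 6.11e-09, 0.788 with an estimated correlation). The member called was hamp, the iron hormone hepcidin, with 77.5 CPM in males and a log2 fold change of 5.90 (SE 0.542). Amino acid and urea-cycle metabolism was higher in males (median 0.56, adjusted p = 1.28e-04, 0.680 with an estimated correlation), with 3 members called: the aminotransferase genes gpt (235 against 751 CPM, 1.72), oat (1.59) and agxt (1.69). Higher in males too were hepatocyte markers (0.61, 0.00128), proteasome (0.41, 0.00128), erythrocyte markers (0.81, 0.00128), interferon response (0.29, 0.00206), apolipoproteins (0.62, 0.00238), gluconeogenesis and glycolysis (0.30, 0.00439), fatty acid oxidation (0.53, 0.00470), exocrine pancreas (2.14, 0.00786), respiratory chain (0.25, 0.0226) and Nrf2 targets (0.37, 0.0409), each with its median and camera adjusted p. With an estimated correlation the egg proteins alone stayed called.

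Within the lists, gnmt, which uses S-adenosylmethionine to methylate glycine, was higher in males (74.1 against 222 CPM, 1.65, SE 0.233), as were aqp7 (4.45), nqo1 (1.43), me1 (5.17), pck2 (1.56), ugt5b1 (1.49) and ifi27.1 (3.08). Lower in males were xbp1, a transcription factor of the unfolded protein response (902 against 167 CPM, -2.19), fth1a (-1.34), acsl1b (-4.88), cyp2k6 (251 against 0.061 CPM, -12.03), nr0b2b (-5.66) and nr1d4a (-3.92). The exocrine pancreas list was higher as a group while its called member, the amylase gene amy2al1, was lower in males (569 against 166 CPM, -1.77).

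Some list medians between sexes rest on single libraries. Without wild-type female 1 the median was 0.13 for proteasome (camera adjusted p = 0.407), 0.11 for nuclear-encoded respiratory chain (0.597), 0.08 for Nrf2 targets and glutathione (0.789), 1.33 for acute phase and complement and 0.98 for apolipoproteins and lipoprotein transport. Without mutant female 1 it was 0.25 for hepatocyte markers (0.0704), 0.44 for acute phase and complement, 1.27 for interferon response and 0.68 for Nrf2 targets and glutathione. Without mutant female 2 it was 0.10 for interferon response (0.295) and 0.15 for Nrf2 targets and glutathione (0.0920). Without wild-type male 1 the adjusted p was 0.120 for nuclear-encoded respiratory chain and 0.156 for Nrf2 targets and glutathione.

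Without mutant male 1 the median was 0.34 for apolipoproteins and lipoprotein transport, 0.45 for gluconeogenesis and glycolysis, 0.51 for erythrocyte markers and 0.57 for Nrf2 targets and glutathione. Without mutant male 2 it was 0.47 for gluconeogenesis and glycolysis and 0.16 for interferon response, and these calls stayed. Exocrine pancreas markers lost their call between sexes without wild-type female 1 (median 1.53, camera adjusted p = 0.128), wild-type male 2 (1.54, 0.0524), mutant female 2 (1.64, 0.201) or mutant male 1 (-0.04, 0.774), and had a median of 4.59 without mutant female 1. With all 8 libraries it was 0.64 (0.603). With mutant female 2 left out in place of wild-type female 2 fatty acid oxidation (0.0905) and apolipoproteins (0.120) lost their calls, and the test direction of exocrine pancreas markers turned (0.689). With a filter of at least 1 CPM in 3 libraries Nrf2 targets and glutathione lost theirs (0.0781).

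The lists not called between sexes, each with median and camera adjusted p, included cell cycle (0.49, 0.0548), mitochondrially encoded genes (0.38, 0.101), methionine cycle (0.19, 0.128), stellate markers (0.48, 0.128), intestine (-1.28, 0.199), heat shock (0.49, 0.247), cholesterol synthesis (-2.08, 0.350) and endothelial markers (0.18, 0.396). Further ones were fatty acid synthesis (-0.01, 0.413), DNA methylation (-0.16, 0.413), xenobiotic metabolism (-0.13, 0.449), unfolded protein response (0.04, 0.481), myeloid (0.12, 0.628), adipocyte (0.22, 0.659), bile acid synthesis (0.20, 0.659), lymphocyte (-0.15, 0.659), arsenic handling (-0.17, 0.677), p53 targets (0.06, 0.682), circadian clock (0.02, 0.767) and biliary markers (0.07, 0.862). Median, mean or test differed in sign for arsenic handling, unfolded protein response, fatty acid synthesis, bile acid synthesis, circadian clock, lymphocyte, biliary and adipocyte lists.

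Whether the genotype difference depends on sex was tested as an interaction, and 15 genes were called. The transcript of igfbp1, a secreted protein that binds insulin-like growth factors, had 197 CPM in wild-type female 1 and 78.1 in the left-out female 2, but 1.82 and 2.19 in the wild-type males, 2.44 and 2.46 in the mutant females and 30.2 and 78.1 in the mutant males. Its interaction was 11.08 (SE 0.791, edgeR adjusted p = 0.0224). The insulin receptor substrates irs2 (6.05, SE 0.421) and irs1 (6.69, SE 0.582, adjusted p = 0.0353) had the same pattern.

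With them went arl4d (6.64), zgc:162608 (7.70), spsb3 (5.86), ypel3 (12.75) and ENSDARG00000099719 (6.46), with positive differences in males and negative ones in females, though none of these was called within either sex alone. Negative were cfhl2, a complement factor H-like gene (-9.42, SE 0.683), with a difference in females of 0.38 (SE 0.396, adjusted p = 0.683), and rh50 (-7.12, SE 0.645). The level of cfhl2 was 76.4 to 166 CPM in 6 libraries and 0.165 and 0.204 in the mutant males. Named after the values were seen were ppp1r3c, which targets a phosphatase to glycogen (9.79), klf11 (7.68), kctd7 (6.24), kctd12 (-4.51) and si:dkey-183n20.15 (-10.98).

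**Figure D4:**
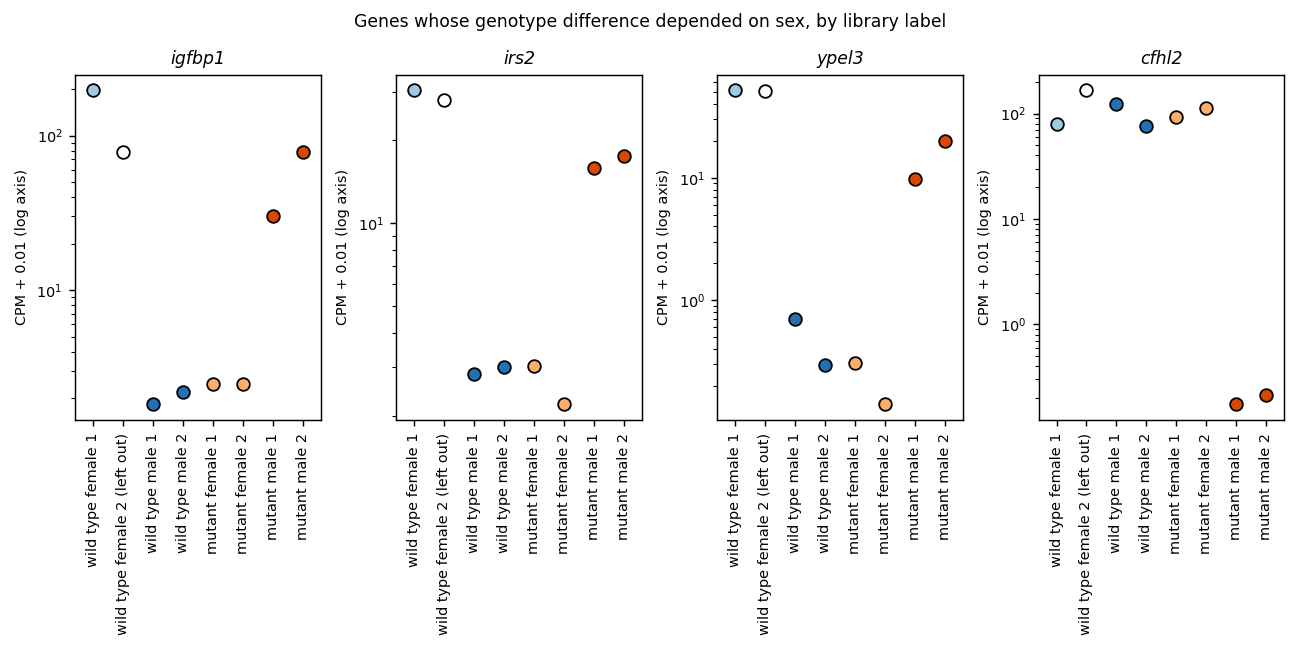
Level of igfbp1, irs2, ypel3 and cfhl2 in each of the 8 libraries as CPM plus 0.01 on a logarithmic vertical axis, 1 point per library, blue for labelled wild type, orange for labelled mutant and white for the left-out wild-type female 2. For igfbp1 the wild-type females and mutant males lie at 30.2 CPM or more and the other 4 libraries at 2.46 or less.

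The count depended on the libraries in the fit: it was 0 without wild-type male 1 or 2 (1602 and 1498 genes at an unadjusted p under 0.05), 1 without mutant male 1 or 2, 82 without mutant female 1 and 398 without mutant female 2. It was 437 with all 8 libraries, 1405 with mutant female 2 left out in place of wild-type female 2, 389 with mutant female 1 left out in place of wild-type female 2, 793 with DESeq2 and 16 with limma-voom, and the 15 genes were within each of these sets but that of limma-voom, which held 11.

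Within males 6 genes were called between genotypes. Levels of cfhl2 (-9.04) and rh50 (-5.06, SE 0.402) fell, and ENSDARG00000103590 (4.18, SE 0.346), itln1 (6.56, SE 0.569), vdac1 (3.94, SE 0.262) and si:ch211-254c8.3 rose, the last from 0 counts. Of these ENSDARG00000103590 was named after its values were seen. The count was 0 without wild-type male 1, mutant male 1 or mutant male 2 (911 to 985 genes at an unadjusted p under 0.05), 1 without wild-type male 2, 17 without wild-type female 1, 113 without mutant female 1 and 114 without mutant female 2. DESeq2 called 398 and limma-voom 48.

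Within females edgeR called 0 genes, with 2204 at an unadjusted p under 0.05, where DESeq2 called 728 and limma-voom 0. The edgeR count was 467 with all 8 libraries, 1497 with mutant female 2 left out in place of wild-type female 2, 2 without mutant female 1 and 263 without mutant female 2. The choice of the library left out follows the labels, and were the genotype labels exchanged, another library would have been meant. For igfbp1 the change in females was -6.32 (SE 0.591, adjusted p = 0.0876) and for ypel3 -7.81 (SE 0.773, adjusted p = 0.104). Across the 6790 genes with a mean of at least 5 CPM, the genotype differences of the 2 sexes had a Spearman correlation of -0.30 (Pearson -0.10) and the same sign in 37.6%. Across all 14885 tested genes the Spearman correlation was -0.16, the Pearson correlation 0.09 (of the other sign) and the same sign held in 41.7%. Genes are not independent replicates, so no p is given.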

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

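Of the tests in this part, those of exchanged labels (in the whole series and in 1 sex), of an aberrant wild-type female library, of depth without the vitellogenin genes and of intestinal tissue were chosen only after the result was seen. The split counts and the tests of linkage, haplotypes, feeding state and total depth were written before it.

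Chance was tested for the counts of both main comparisons by regrouping the libraries, but 1 of 34 is the smallest share this can give. Each other split also keeps the labelled difference in its residual spread, which can lower its count. The splits therefore do not exclude chance. Of 34 splits of the 7 libraries into 4 and 3, 1 gave as many called genes as the labelled genotypes, the labelled split itself, with 9 genes against 6 in the highest other. For the sexes 1 of 34 splits gave as many, the labelled one, with 248 genes against 132.

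Genes such as vdac1 and itln1 differed between the labelled genotypes, and the source of the difference stays open. Linkage to as3mt was tested among its 150 neighbours on each side (1 of 139 tested genes against 135 of 10353 elsewhere at an unadjusted p under 0.01, Fisher 1-sided p = 0.839), and haplotypes of the 2 lines by neighbouring pairs of such genes (18 pairs, 12 of them on 2 chromosomes, against a permuted median of 8, permutation p = 0.003). For genotype the pairs lay beyond the upper limit of the permutations, which was 14. Neighbouring pairs were also in excess for sex (238 against a permuted median of 196 and an upper limit of 223, permutation p = 0.001). In proportion to the median the excess was smaller for sex than for genotype. For the interaction the 161 pairs lay above the permuted median of 140 and just within the upper limit of 163 (permutation p = 0.0365). An excess was thus not seen for genotype alone. Only 70.5% of tested genes could be placed in the gene order. Of the 238 genes at an unadjusted p under 0.01, 136 (57.1%) could be placed. Neither test therefore decides on linkage or haplotypes. The as3mt log2 fold change of 0.49 (adjusted p = 1.00) cannot tell whether the genotype labels were exchanged in the whole series, which would turn every direction given for genotype. Line, birth cohort and the mutation itself go together in this design and were not tested apart.

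The genotype difference itself differed between the sexes by the edgeR interaction for 10 named genes, with male minus female values of 6.05 (irs2), 6.64 (arl4d), 11.08 (igfbp1), -9.42 (cfhl2), 7.70 (zgc:162608), 5.86 (spsb3), 12.75 (ypel3), 6.69 (irs1), -7.12 (rh50) and 6.46 (ENSDARG00000099719), where only cfhl2 and rh50 were also called within males and none within females. Genotype labels exchanged in 1 sex would make on-off genes divide the 8 libraries by the crossed classes, but 0 did, against 10 by labelled genotype, 6 by sex and at most 2 in 32 other splits. The left-out female 2 lay nearer to wild-type female 1 than to the mutant females for 14 of the 15 called genes. For those genes this argues against a wild-type female 1 that is aberrant alone. It rests on 1 library that the submitters left out, and a state shared by both wild-type females would give the same outcome. Feeding state at dissection may differ between groups, since igfbp1 and irs2 are repressed by insulin, but 17 other insulin-repressed genes had a median interaction of 0.15, 10 positive and 0 called by edgeR (camera p = 0.121, 0.419 with an estimated correlation), which decides neither way. A difference between the sexes in the effect of genotype, line or age stays open as untested, and the edgeR calls were lost without wild-type male 1 or 2 (0 called).

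Mutant female 1 lay apart from the other libraries labelled mutant with a level of 1.96 for intestine markers. Among females it lay apart with 2.73 for cholesterol synthesis and 0.32 for arsenic handling. For arsenic handling it did not lie apart from all livers, since the wild-type males had 0.26 and 0.22. Its correlation with mutant female 2 was 0.877, and 0.876 after thinning to equal total counts, against 0.951 between the wild-type females, and 0.880 against 0.956 after thinning to equal counts without the vitellogenin genes, so depth is not the source. A first test of intestinal tissue came out against it, since between the mutant females exocrine pancreas markers differed by 5.17 and intestine markers by 1.80, and a second was then chosen because mutant female 2 has the lowest pancreas level of the 8. In the second, 7 of 14 intestine markers lay at least 4 times above every other library (fabp2 at 699 CPM, and, named after their values were seen, slc5a1 at 319 and the anpep copy ENSDARG00000103878 at 371, while the copy ENSDARG00000097285 had 4.68, the lowest of the 8), but this restates the level that prompted it, 9 of the 14 reach 5 CPM in another library and 2 stand in another list, so intestinal tissue stays open. For cholesterol synthesis the difference between the mutant females was 3.40, beyond the intestine median but inside that list's quartiles (-0.004 to 5.39), so tissue and a change in the liver cannot be told apart.

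The left-out wild-type female 2 had an egg protein level of 9.01, against 7.48 to 7.69 in the other females. Of 102 groups of libraries tested for a library far from the rest, 4 met the limit where 5.1 are due by chance, since chance flags about 1 in 20 groups.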

How the results depend on the processing

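The alternative with mutant female 1 left out was chosen after seeing the data. Counts below are by edgeR unless said, and the cause of each move was not tested. The genotype count of 9 became 32 with no low-count filter, 233 with DESeq2, 72 with limma-voom, 25 with all 8 libraries, 38 with mutant female 2 and 33 with mutant female 1 left out in place of wild-type female 2, 19 with no sex term and 0 at an adjusted p under 0.01 (778 at an unadjusted p under 0.05). Without 1 library it was 0 to 27. The 9 genes stayed among those called in all of these but the last, and without mutant female 1 or 2, while 6 stayed without wild-type female 1 and 0 without any 1 male. The sex count of 248 became 1056 with DESeq2, 381 with limma-voom, 773 with all 8 libraries, 406 and 1078 with mutant female 2 or 1 left out in place, 425 with no genotype term, 72 at an adjusted p under 0.01 and 135 for a fold of at least 1.5, and 82 to 387 without 1 library. The interaction count of 15 became 25 with vitellogenin genes left out of the scaling, 152 with no filter, 39 with at least 1 CPM in 3 libraries, 793 with DESeq2, 437 with all 8 libraries, 1405 and 389 with mutant female 2 or 1 left out in place and 0 at an adjusted p under 0.01 (2276 at an unadjusted p under 0.05). It was 0 to 398 without 1 library. With no filter the median of all genes for the interaction was -0.28. Wild-type female 1 could not be left out for the interaction or the females, since no wild-type female would remain. For the same reason the genotype values without it compare males only, and the sex values without it compare labelled mutants only. The count of 6 in males became 104 with no filter, 398 with DESeq2, 48 with limma-voom, 67 with all 8 libraries, 176 and 181 with mutant female 2 or 1 left out in place and 0 at an adjusted p under 0.01 (1304 at an unadjusted p under 0.05), and 0 to 114 without 1 library. The count of 0 in females (2204 at an unadjusted p under 0.05, 0 with limma-voom) became 50 with no filter, 728 with DESeq2, 467 with all 8 libraries, 1497 and 202 with mutant female 2 or 1 left out in place, and 0 to 263 without 1 library. The as3mt log2 fold change stayed positive and not called, at 0.23 without wild-type male 2 to 0.91 without wild-type female 1 (males only). The 2 lists called between genotypes became 6 with no filter, 4 and 6 with mutant female 2 or 1 left out in place, 5 with no sex term and 0 with the estimated correlation, and 2 to 13 without 1 library, while the interferon list was called in 16 of 16 settings with the preset correlation. The 14 lists called between sexes became 1 with the estimated correlation and 12 to 15 without 1 library. Of 1144 alternative values for 63 named genes, 924 kept their side of the threshold, 220 lost it and 0 turned direction. At a fold of 2 the genotype test recovered 0 of 50 simulated genes.

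The counts gave no sign that the numbers in the labels pair the fish: differences between numbers 1 and 2 correlated at -0.18 to 0.01 between groups. That 0 libraries correlated best with their own number follows from the same differences. A pairing without a trace in the counts cannot be excluded. With the number as a block 0 genes were called by edgeR between genotypes (644 at an unadjusted p under 0.05), 94 between sexes, and 4 and 14 lists. The as3mt log2 fold change was 0.56 with the block.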

Other observations

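In this part the interaction over gene lists was chosen only after the data were seen. It was also fitted with 2 choices changed at once, mutant female 1 left out and wild-type female 2 put back, called the exchanged set here. A move there cannot by itself be put down to either library. With all 8 libraries, where only wild-type female 2 was put back, cytosolic ribosomal proteins were called upward (camera adjusted p = 0.00226). Their call was lost only once mutant female 1 was left out as well. Exocrine pancreas markers were not called with all 8 libraries (camera adjusted p = 0.194, upward). Transcripts of cholesterol synthesis, the sterol pathway from acetyl-CoA, had a median genotype difference of -2.50 in males and 3.31 in females, an interaction of -5.24 (camera adjusted p = 1.28e-07, adjusted p = 0.981 with an estimated correlation). The difference in females rested on mutant female 1, at a list level of 2.73. The level was -0.83 in mutant female 2, -0.92 in wild-type female 1 and -0.34 in the left-out female 2. The difference in males did not involve that library: the level was 0.36 and 1.42 in the wild-type males and -1.76 and -0.95 in the mutant males. In the exchanged set, without mutant female 1, the interaction was -1.88, in the same direction, with mutant female 2 as the only mutant female. Acute phase and complement transcripts had an interaction of 1.19 (adjusted p = 2.18e-05, 0.981 with an estimated correlation), and 0.65 in the exchanged set (adjusted p = 0.0202). Myeloid markers had 0.71 (1.59e-04, 0.981 with an estimated correlation), and 1.07 in the exchanged set (6.53e-04). Exocrine pancreas markers had -1.35 and no call (0.760, 0.981 with an estimated correlation), and 7.55 in the exchanged set (0.00153).

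Proteasome subunits had an interaction of -0.69 (camera adjusted p = 0.00102, 0.981 with an estimated correlation), and -0.61 in the exchanged set (6.53e-04). Cytosolic ribosomal proteins had 0.57 (0.00102, 0.981 with an estimated correlation), and 0.23 with no call in the exchanged set (0.261). Of 34 lists 13 were called with the preset correlation, 5 upward and 8 downward, and 0 with an estimated one. In the exchanged set the preset correlation gave 10, with 6 in both and the same direction in 6.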
